A study of Homo sapiens with 12 samples.

How the data were processed

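Total RNA from 12 samples of LNCaP, a human prostate cancer cell line, was labelled with biotin and hybridised to Illumina HumanHT-12 bead arrays, which read each transcript with a short probe coupled to beads. Per the labels, 6 arrays came from cells given a plasmid with the full-length FOXA1 cDNA and 6 from cells given the same plasmid backbone with GFP, all harvested 48 h after transfection. Each array was assigned to its group and replicate number by its title. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

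The authors deposited 2 tables of the same arrays, both on a log2 scale: one that its header calls non-normalized, with 48107 probes, and one of normalized values with 47323 probes. In the deposited non-normalized table, log2 medians and quartiles differed between arrays. In the deposited normalized table the 12 column medians lay between 7.428 and 7.429, and the rank order of probes within each array was that of the first table, as quantile normalization gives. The background correction, the summary program and the normalization program are not given in the sources used here. The 784 further probes of the non-normalized table have no stated role. Their normalised log2 values had a median of 7.25 and a 95th percentile of 7.54, and this percentile serves here as an estimate of background, with which the mean of a gene over all 12 arrays is compared. Shares of probes above background were counted before normalization, on each array against the 95th percentile of these probes on that array.

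The test design assumed linear intensities with detection p-values. The table was already on the log2 scale and came without detection p-values, so the fallbacks written for that case were used: quantile normalization of the log2 values with no further background correction, and a filter that kept probes whose mean log2 value over all 12 arrays lay above the median of all probes. The filter ignores group. The 6 probes with a missing value were left out. Probes were named through the platform annotation, in which 30113 probes had 1 gene symbol and 8 had several, while 17202 probes of the normalized table were unlisted and are unnamed here. The entrez identifiers updated 0 symbols, and 3 genes of the lists were matched through a newer symbol. Of 23658 kept probes, 16483 had 1 symbol, and the probe with the highest mean was used for each gene, which left 12420 genes. No position is given for any probe, since the files name no genome build.

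The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, FOXA1 minus GFP, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no covariate. Log2 differences are FOXA1 minus GFP throughout. Single values and list means were also compared by exact permutation over all 924 arrangements of 6 against 6 arrays, two-sided, for which the smallest possible p is 0.00216. The 24 gene lists, with 628 distinct genes, of which 478 were measured, were tested with limma's camera at a preset inter-gene correlation of 0.01 and a Benjamini-Hochberg threshold of 0.05 over the lists. Camera with an estimated correlation and fry stood beside it. Some listed genes are not analysed here, and their number is the difference between listed and measured genes.

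The groups, the main test, the filter, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named FOXA1, the 12 largest changes each way among genes past the threshold or, if none passed, the 5 genes with the smallest p in each direction, up to 4 members of each list with the smallest p, and a few androgen-regulated genes whatever their p. Here up to 4 members were named for lists past the threshold and 2 for the others; this split was made after the list results were seen. Genes of the rule that are not analysed here are not reported.

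The fit was tested on simulated data made from the real residuals of these 12 arrays, over 12420 genes with 200 changed genes, 50 of each size, and 20 runs. At the threshold, 24.1% of genes changed 1.25-fold were called, 83.3% at 1.5-fold, 97.7% at 2-fold and 99.9% at 3-fold. Residuals about group means are smaller than the noise, and with residuals rescaled for this 79.9% were called at 1.5-fold. A shift of 0.1 on the log2 scale given to all members of the androgen-induced list put that list past the camera threshold in 16 of 20 runs. A mean of 0 other lists passed in these runs, while other splits of the real arrays gave a median of 4. The runs therefore do not show how often the preset correlation calls a list falsely on these arrays. The number of arrays limits the precision: the median half-width of the 95% interval of a gene's log2 difference was 0.217, which is 1.16-fold.

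The alternatives covered median centring, the authors' normalized table, no filter, a mean over the probes of a gene, moderation with a variance trend, array weights, the replicate number as a block, each array left out in turn, stricter thresholds, all kept probes, and other set tests. Normexp background correction with an offset of 50, a filter at the upper quartile, the leading component of the residuals as a covariate, and a fit without 3 arrays were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.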

Results

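LNCaP cells, an androgen-responsive line derived from a prostate cancer metastasis, were transfected with a FOXA1 plasmid or with a GFP control plasmid, and gene expression was measured on 12 arrays, 6 per group, 48 h later. The comparison asks how overexpression of FOXA1, a pioneer transcription factor that opens chromatin for nuclear receptors in prostate and breast epithelium, affects gene expression in this line. Before normalization the median log2 intensity of the arrays lay between 7.31 and 7.63, and between 32.8% and 36.4% of an array's probes stood above the 95th percentile of the background probes of that array. After normalization, Pearson's r across the 12420 genes lay between 0.968 and 0.995 for pairs of arrays (genes are not independent replicates). No 2 arrays held identical values.

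FOXA1 itself was already among the brightest genes of the control cells, at the 97.7th percentile of all genes tested. Its level was 13.44 ± 0.13 (SD, n = 6) in the FOXA1 arrays and 13.31 ± 0.17 (SD, n = 6) in the GFP arrays, in normalised log2 intensity. The difference was 0.13 with a standard error of 0.09 and a 95% interval from -0.07 to 0.33, so that an increase above 1.25-fold lay outside the interval. It did not exceed the spread between arrays (exact permutation p = 0.167, n = 6 against 6), and 2 of the 6 FOXA1 arrays lay above every GFP array. FOXA1 was read by 1 probe, and the sources used here do not say which part of the transcript it covers, so it is not known here whether it reads the plasmid's transcript or the endogenous one alone. The difference was positive in every alternative and with each array left out; of single arrays left out, GFP 2 gave the lowest value, 0.07, and it was 0.04 without GFP 3, FOXA1 4 and FOXA1 3 together.

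**Figure D1:**
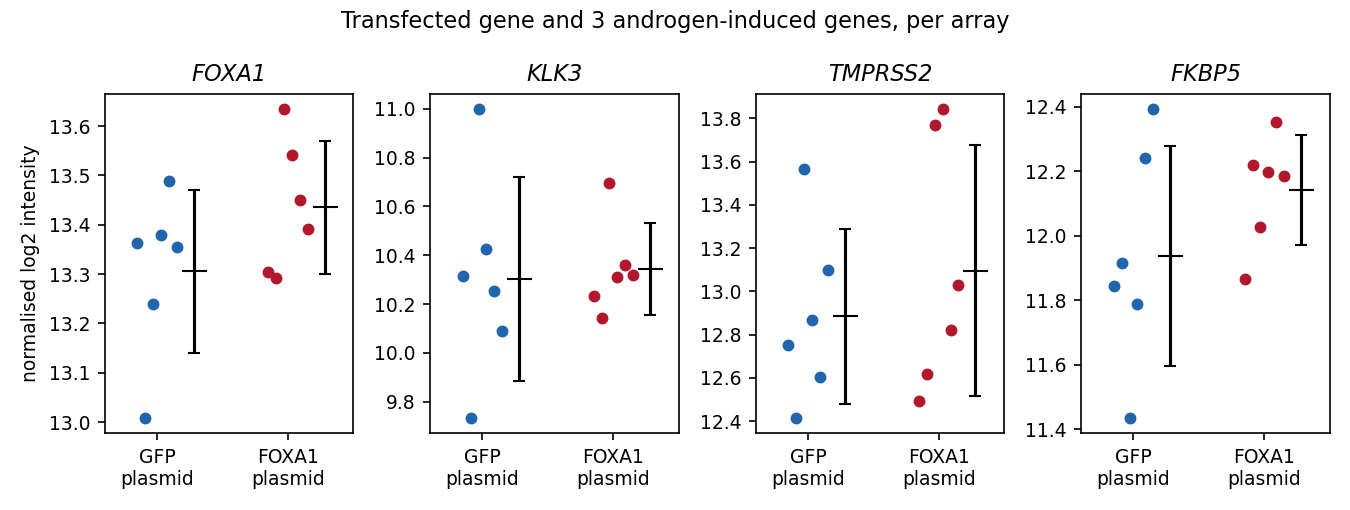
Normalised log2 intensity of FOXA1, KLK3, TMPRSS2 and FKBP5 on each of the 6 GFP arrays (blue points) and 6 FOXA1 arrays (red points), with the group mean and SD (black bars). The vertical axis differs between panels, and the groups overlap in each, with mean differences of 0.13, 0.04, 0.21 and 0.21.

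Across the genome, 0 of 12420 genes passed an adjusted p of 0.05 in limma, higher or lower. At an unadjusted p under 0.05 there were 206 genes, 98 higher and 108 lower in the FOXA1 arrays, where 621 would be met with no effect and independent genes. This fit ignores the replicate number. With the number as a block, 342 genes lay under that p and 0 passed the adjusted threshold. The groups did not overlap for 8 genes, 0.0644% of the genes against 0.216% by chance. The median gene differed by 0.01. The 95% interval excluded a 2-fold difference of intensity in either direction for 99.9% of genes and a 1.5-fold difference for 96.8%. Intensities were not corrected for background, so for genes near background this says little about the transcript.

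The genes with the smallest p did not pass the threshold (each with an adjusted p of 1.00 in limma), and they are given as values. ODAD3, which encodes a component of the docking complex of ciliary dynein arms, was the 1 gene with a fitted difference of 1.5-fold or more: 8.31 ± 0.38 (SD, n = 6) against 7.62 ± 0.18 (SD, n = 6), a difference of 0.69 with a standard error of 0.15, with 6 of 6 FOXA1 arrays above every GFP array. MAP3K14, the kinase of the non-canonical NF-kB pathway, differed by 0.35, TUB by 0.24, HSFX1 by 0.28 and ALKAL1 by 0.26. In the other direction, SHROOM4, an actin-binding protein, had 9.79 ± 0.14 (SD, n = 6) against 10.34 ± 0.36 (SD, n = 6), a difference of -0.56 with a standard error of 0.14, with 6 of 6 FOXA1 arrays below every GFP array. TRIM13, a ubiquitin ligase of the endoplasmic reticulum, differed by -0.42, STRIP2 by -0.34, ANKRD28 by -0.28 and ZNF385D by -0.25. HSFX1, ALKAL1 and ZNF385D did not stand above the background estimate in their mean over all 12 arrays. Other kept probes gave -0.03 for SHROOM4, 0.01 for ANKRD28, -0.00193, 0.08 and 0.04 for TRIM13 and -0.11 for ALKAL1, with mean levels of 7.55, 7.62, 7.60, 7.52, 7.83 and 7.44. Those other than the TRIM13 probe at 7.83 lay near or below the background estimate of 7.54 and say little about these genes.

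Androgen-induced genes, the group most tied to FOXA1 in prostate cells, stood slightly higher in the FOXA1 arrays as a list. Of 46 measured members 37 were higher and 9 lower, with a median difference of 0.06, and the list passed camera (adjusted p = 0.0236 with limma's preset correlation). The call was lost with an estimated correlation (adjusted p = 0.574 with an estimated correlation). The list mean differed by 0.08 with a 95% interval from -0.02 to 0.17 (exact permutation p = 0.0887, adjusted over the 24 lists 0.909). A single list at the smallest possible exact p, 0.00216, would not pass over 24 lists, so the adjusted value alone decides nothing. Of its members 0 rose and 0 fell, over all genes and adjusted over the list alone. KLK3, which encodes prostate-specific antigen, differed by 0.04 ± 0.16 (SE), and its sign turned when FOXA1 3, GFP 2 or GFP 6 was left out. TMPRSS2, a transmembrane protease, differed by 0.21 ± 0.24 (SE), and FKBP5, a co-chaperone of steroid receptors, by 0.21 ± 0.14 (SE). With single arrays left out, TMPRSS2 ran from 0.06 (FOXA1 4) to 0.34 (GFP 3) and FKBP5 from 0.11 (GFP 3) to 0.30 (GFP 6). The members with the smallest p were the kinase STK39 with 0.22, spermine synthase SMS with 0.24, the receptor kinase MERTK with 0.20, whose other probe lay at 0.04, and TARP with 0.32. The call also ended without FOXA1 3 (adjusted p = 0.0679), FOXA1 5 (0.205), FOXA1 6 (0.0527), GFP 2 (0.117) or GFP 3 (0.0541), with median centring (0.0789) and with a mean over probes (0.0526). It held in 18 of 27 settings, and the list's direction was the same in all 27. The lowest adjusted p in camera was 0.000992, with the replicate number as a block, against 0.523 under the block with an estimated correlation. With single arrays left out, the list median ran from 0.04 (FOXA1 5) to 0.09 (GFP 3).

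Androgen-repressed genes leaned the other way without passing the test. Of 10 measured members 8 were lower and 2 higher, with a median of -0.08 (limma's camera adjusted p = 0.121). MET, the receptor of hepatocyte growth factor, differed by -0.20, and CAMK2N1, an inhibitor of calmodulin-dependent kinase, by -0.32. Of the members 0 passed over all genes or adjusted over the list alone. The list passed in the fit without FOXA1 1 (adjusted p = 0.0488), with the filter at the upper quartile (0.0449) and with the replicate number as a block (0.0222), each by the preset correlation and none with an estimated one (0.320, 0.594 and 0.523). Its median ran from -0.13 without GFP 5 to -0.01 without GFP 4, and CAMK2N1 from -0.47 without GFP 4 to -0.09 without GFP 3.

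Heat shock genes had the smallest p of any list. Of 17 measured members 16 were higher and 1 lower in the FOXA1 arrays, with a median of 0.10 (limma's camera adjusted p = 0.00688 with the preset correlation, 0.574 with an estimated correlation). The inducible chaperone HSPA1B differed by 0.34, HSP90AB1 by 0.27, the constitutive chaperone HSPA8 by 0.19 and HSP90AA1 by 0.15. Of these genes 0 passed over all genes or adjusted over the list alone. The call at the preset correlation rested on 1 control array: without GFP 3, where the list mean stood at -0.39 relative to the mean of all arrays, the adjusted p was 0.510. Median centring also ended the call (adjusted p = 0.115).

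Cholesterol and fatty acid synthesis genes were higher by a median of 0.13, with 20 of 25 measured members higher and 5 lower (limma's camera adjusted p = 0.0255 with the preset correlation, 0.748 with an estimated correlation). Lanosterol synthase, LSS, differed by 0.31, HMGCS1, which makes the precursor of mevalonate, by 0.20 and the sterol demethylation enzyme MSMO1 by 0.16, while HSD17B7 lay at -0.28. LSS had a second probe, near background, at 0.10, and MSMO1 had other probes at -0.03 and 0.03. Of the members 0 passed over all genes or adjusted over the list alone. The call at the preset correlation also ended with median centring (0.0722), with a mean over probes (0.0678) and without FOXA1 2 (0.0973), FOXA1 3 (0.0633), FOXA1 4 (0.320), FOXA1 6 (0.0538), GFP 3 (0.0702) or GFP 5 (0.543).

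The proliferation lists were also past the preset test. DNA replication genes had 27 of 32 members higher and 5 lower, with a median of 0.07 (limma's camera adjusted p = 0.0236), and mitosis genes had 27 of 36 higher and 9 lower, with a median of 0.08 (adjusted p = 0.0468). Both calls were lost with an estimated correlation (adjusted p = 0.786 and adjusted p = 0.809 with an estimated correlation). Among replication genes, UNG, a uracil glycosylase, differed by 0.22, the ribonucleotide reductase subunit RRM1 by 0.14, the helicase subunit MCM4 by 0.24 and UHRF1 by 0.24, while the other, dimmer probe of UNG (8.02) lay at -0.03. Among mitosis genes, the checkpoint kinase BUB1B differed by 0.36, the spindle factor TPX2 by 0.24, and the kinesins CENPE and KIF20A by 0.15 each. In both lists 0 members passed over all genes or adjusted over the list alone. Both medians turned sign, to -0.00478 and -0.0439, without the 3 arrays that lay farthest along the leading component of the residuals (GFP 3, FOXA1 4 and FOXA1 3). Both calls also ended without FOXA1 1, FOXA1 2, FOXA1 4, FOXA1 6, GFP 3 or GFP 5 (adjusted p from 0.0929 to 0.945 for replication and from 0.0717 to 0.948 for mitosis), the mitosis call without FOXA1 3 (0.196), and both with median centring, no filter, a mean over probes, or array weights.

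**Figure D2:**
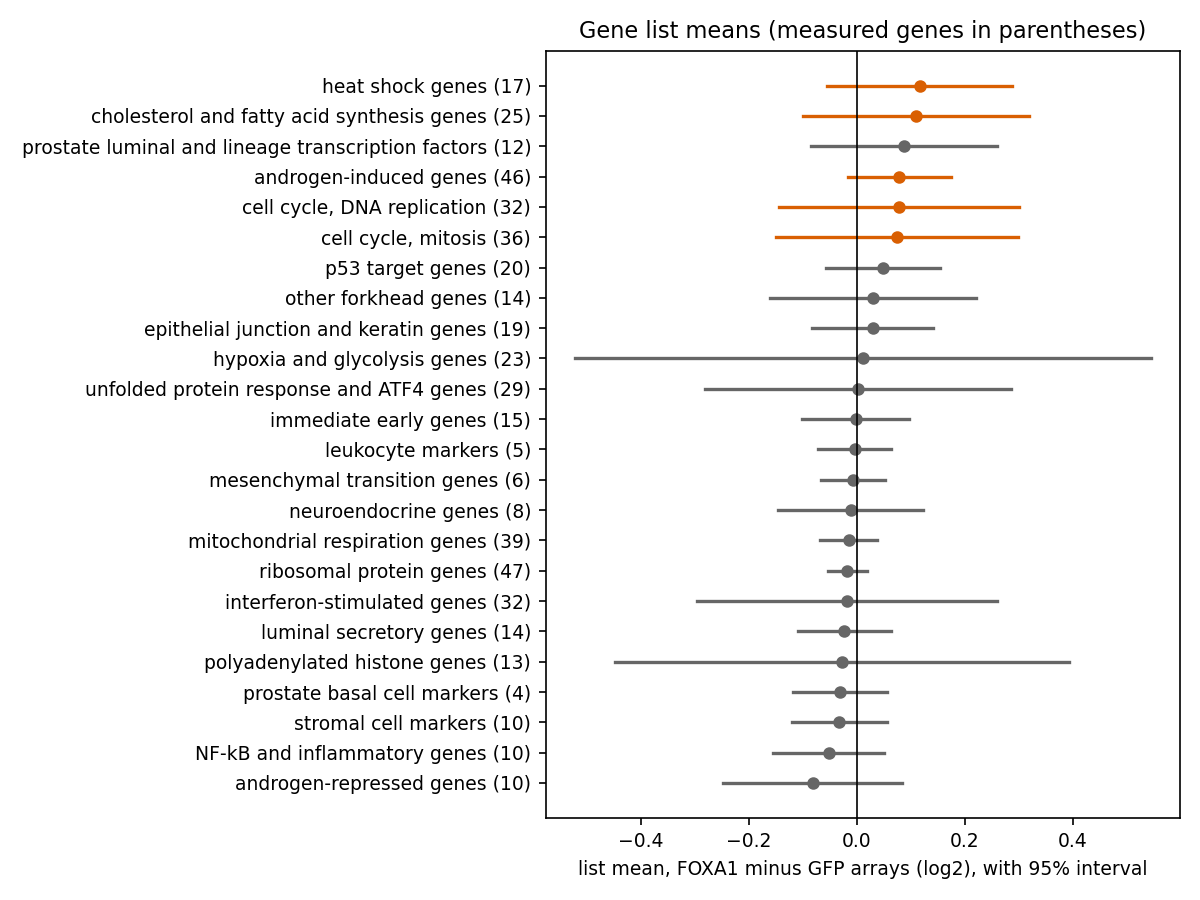
Difference of list means, FOXA1 minus GFP arrays, on the log2 scale for 24 gene lists (points), with the 95% interval from the spread between arrays (lines) and the number of measured genes in parentheses. The 5 lists past camera with the preset correlation are in orange, and every interval includes 0.

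The other lists tied to prostate epithelium did not pass camera. Luminal and lineage transcription factors had a median of 0.07 with 8 of 12 members higher (limma's camera adjusted p = 0.341). GRHL2, a regulator of epithelial identity, differed by 0.36 and GATA3 by 0.22, the latter not above the background estimate. Other forkhead genes had a median of 0.04 with 10 of 14 higher (adjusted p = 0.769), with FOXO4 at -0.13 and FOXP4 at 0.10. Luminal secretory genes had a median of -0.02, which turned positive with median centring, with 10 of 14 lower (adjusted p = 0.598), with ANXA9 at -0.11 and MSMB at -0.09. Epithelial junction and keratin genes had a median of 0.05 with 11 of 19 higher (adjusted p = 0.866); the median fell below 0 without FOXA1 3 (-0.00607), FOXA1 4 or GFP 2 and was highest without GFP 6 (0.14). Their plakophilin PKP3 lay at 0.23 and claudin CLDN4 at -0.19. Mesenchymal transition genes had a median of -0.01, positive with median centring, over 6 members (adjusted p = 0.822), with ZEB2 at -0.07, its other probe at 0.06, and SPARC at -0.04, neither above the background estimate. Neuroendocrine genes had a median of -0.00147, positive with median centring, over 8 members (adjusted p = 0.769), with CHGA at -0.07 and STMN2 at -0.05, neither above the background estimate.

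Stress and signalling lists did not pass either. The p53 target list had a median of 0.07 with 14 of 20 higher (limma's camera adjusted p = 0.505), with MDM2, the ligase that turns over p53, at 0.19 and the apoptosis gene BBC3 at -0.13. NF-kB and inflammatory genes had a median of -0.03 with 8 of 10 lower (adjusted p = 0.341), with the chemokine CCL5 at -0.27 and the inhibitor NFKBIA at -0.15. Interferon-stimulated genes had a median of -0.04, positive with median centring, with 18 of 32 lower (adjusted p = 0.865), while the proteasome subunit PSMB9, not above the background estimate, lay at 0.19 and TRIM21 at 0.13. Without FOXA1 5 the interferon list passed as lower with the preset correlation (adjusted p = 0.0107) and not with an estimated one (adjusted p = 0.571). Unfolded protein response genes had a median of 0.01 over 29 members, with camera's direction lower (adjusted p = 0.875), and the median ran from -0.06 without GFP 2 to 0.10 without GFP 3, below 0 also without FOXA1 3, FOXA1 5, GFP 1 or GFP 4, with DNAJC3 at -0.12 and the serine synthesis enzyme PHGDH at 0.15. Immediate early genes had a median of 0.02 over 15 members and a list mean of -0.00245, with camera's direction lower (adjusted p = 0.836), and with IER2 at -0.12 and KLF6 at -0.12.

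Housekeeping and metabolic lists did not pass camera, and ribosomal protein and mitochondrial genes had the narrowest intervals of list means. Ribosomal protein genes had a median of -0.02 with 26 of 47 lower (limma's camera adjusted p = 0.442). RPS12 had 15.61 ± 0.03 (SD, n = 6) against 15.72 ± 0.05 (SD, n = 6), a difference of -0.11, with 6 of 6 FOXA1 arrays below every GFP array and an adjusted p of 1.00 in limma, and RPL12 differed by -0.15 with its other probe at 0.02. Mitochondrial respiration genes had a median of -0.00439 over 39 members (adjusted p = 0.574), with UQCRB at 0.15, its other, much dimmer probes (mean levels 7.89 and 7.52) at -0.05 and -0.07, and ATP5F1C at -0.23. Under median centring both lists passed camera as lower than other genes (adjusted p = 2.6e-13 and adjusted p = 0.000144) with the preset correlation, and not with an estimated one (adjusted p = 0.787 and adjusted p = 0.840). Hypoxia and glycolysis genes had a median of -0.000168 over 23 members and a list mean of 0.01, with camera's direction lower (adjusted p = 0.946), and P4HA2 at -0.13 and ADM at -0.12. The hypoxia list passed as higher without GFP 3 (adjusted p = 0.00501) and as lower without FOXA1 3 (adjusted p = 0.00603), both with the preset correlation and neither with an estimated one (adjusted p = 0.678 and adjusted p = 0.803). Polyadenylated histone genes had a median of -0.01 over 13 members (adjusted p = 0.946), with H3-3B at 0.10 and H4C3 at -0.21.

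Markers of cell types that LNCaP cultures should lack had low list means and did not pass camera. For comparison, the background estimate was 7.54 and the median of kept genes 8.69. Only 4 of 12 basal, 10 of 15 stromal and 5 of 13 leukocyte markers were measured. Basal cell markers averaged 7.57 ± 0.07 (SD, n = 6) in the FOXA1 arrays and 7.60 ± 0.06 (SD, n = 6) in the GFP arrays (limma's camera adjusted p = 0.591), with SERPINB5 at a difference of 0.10 and ITGB4, not above the background estimate, at -0.09. Stromal markers averaged 7.76 ± 0.06 and 7.79 ± 0.08 (SD, n = 6 each; limma's camera adjusted p = 0.591), with MYL9, not above the background estimate, at -0.13 and POSTN at -0.12. Leukocyte markers averaged 7.82 in both groups (adjusted p = 0.946), with MS4A1 at 0.14 and CD2 at -0.14. In each of the lists that did not pass camera, 0 members passed over all genes or adjusted over the list alone.

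Several lists varied far more between arrays of one group than between the groups. The mean of hypoxia and glycolysis genes spanned 2.19-fold over the 12 arrays, with an SD of 0.415 within groups, and was highest on GFP 3 (0.78 above the mean of all arrays) and FOXA1 3 (0.71). The glycolytic regulator PFKFB4 spanned 2.29 on the log2 scale, the collagen hydroxylase P4HA1 1.94, ANKRD37 1.88, NDRG1 1.87, hexokinase HK2 1.81 and PGK1 1.78; these 6 were chosen after their values were seen. Interferon-stimulated genes spanned 1.51-fold and were highest on GFP 5 (0.41) and FOXA1 5 (0.39). Polyadenylated histone genes spanned 1.86-fold and were highest on the same arrays (0.53 and 0.45).

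**Figure D3:**
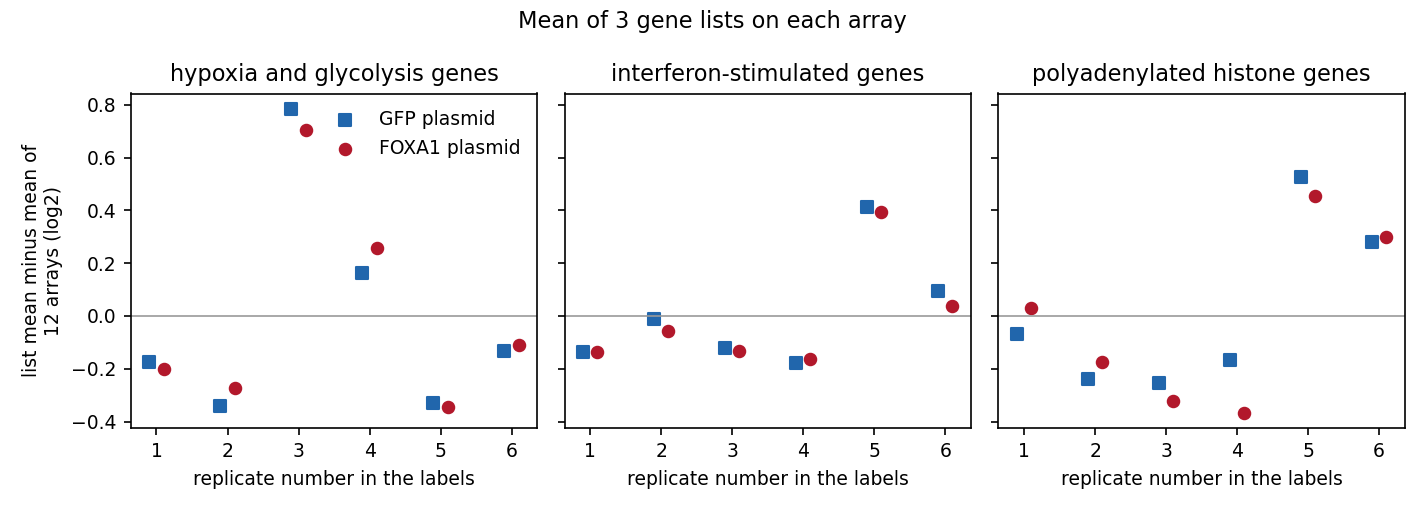
Mean of 3 gene lists on each array, minus the mean over all 12 arrays (log2), by the replicate number of the labels, for GFP arrays (blue squares) and FOXA1 arrays (red circles). Arrays of number 3 are highest for hypoxia and glycolysis genes (0.78 and 0.71) and arrays of number 5 for interferon-stimulated genes (0.41 and 0.39).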

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

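Chosen after the results were seen were the tests with the leading residual component, with the estimated correlation as an explanation, with the interval of 1.5-fold changes, with splits that part each replicate number, and those of array brightness, of replicate number and of FOXA1 by number for the hypoxia list.

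Within groups of 6 arrays, 1 array stood apart from the other 5 by more than Dixon's 95% bound in 9 of 192 group values tested, where chance gives about 9.6. The gap as a share of the group's range is given for each. On FOXA1 3 the hypoxia-induced genes P4HA2 (0.745, 9.34 against 8.61 to 8.80) and ADM (0.808, 8.21 against 7.55 to 7.68) were high. On GFP 3, ADM (0.691, 8.70 against 7.49 to 7.86) and POSTN (0.675, 7.91 against 7.62 to 7.71) were high. RPL12 was low on FOXA1 4 (0.760), and ITGB4, near background, was high on FOXA1 6 (0.770). On FOXA1 5 the means of interferon-stimulated genes (0.640) and of NF-kB and inflammatory genes (0.659) were high. The mean of p53 target genes was low on GFP 2 (0.714).

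No gene passed the threshold, and FOXA1 itself differed by 0.13. Too few arrays is argued against for changes of 2-fold if as many genes changed as were simulated, 200. Of genes given such a change on these residuals 97.7% were called (94% to 100% over 20 runs). Fewer changed genes, for which the adjustment is stricter, were not simulated. Missed intensity differences of 1.5-fold are argued against for most genes, since the 95% interval excluded them for 96.8% of genes. For the other genes they stay open. Over all simulated genes 83.3% of such changes were called (76% to 92%), and 79.9% with rescaled residuals (66% to 96%). These shares need not hold for genes with wide intervals. The intervals are of intensity without background correction, so for genes near background they say little about the transcript. Variation shared by many genes and unrelated to group could hide changes. Its leading component alone is argued against as the whole reason: with that component of the residuals as a covariate, 0 genes passed in limma. With this covariate 447 genes had an unadjusted p under 0.05, against 206 in the main fit. Only the leading component was removed, so shared variation along the other components stays open. In 100 drawn splits of the 12 arrays, the real one included, the count of 0 called genes decides nothing, since all 100 hold at least 0 (the highest other gave 1), while at an unadjusted p under 0.05 the real 206 compares with up to 2136 in another split, which points to a structure of the arrays other than their group. A small effect of FOXA1, or a low rise or no rise of FOXA1 protein in cells that already express it, stays open and was not tested. These arrays do not show that the plasmid raised FOXA1. Its 1 probe did not differ beyond the spread between arrays, and whether it reads the plasmid's transcript is not known here.

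The 5 lists past camera with the preset correlation, led by heat shock and androgen-induced genes, are not set apart from chance. Of 100 splits, the real one included, 35 gave at least 5 lists, and the highest other gave 8. A further 32 splits, again with the real one, part the arrays of each replicate number. These spread variation shared by a number evenly over the groups. Of them 2 gave at least 5 lists, the real one included (6.25%, where the least possible is 3.125%), and the highest other gave 5. With the correlation of the genes within each list estimated from the arrays, 0 lists passed. The estimates were 0.0488 (androgen-induced), 0.437 (replication), 0.434 (mitosis), 0.173 (heat shock) and 0.197 (cholesterol), each above the preset 0.01. By these estimates, genes of the 5 lists varied together more than the preset allows. But this setting also gave 0 lists in every other split, and no simulated run reported here shows that it can call a shifted list. Its count of 0 therefore cannot tell such shared variation from a test with little power. Counted with the real grouping, the androgen-induced list passed in 16 of 100 splits and 2 of the 32, and the heat shock list in 24 and 4. The cholesterol list passed in 25 and 4, the mitosis list in 47 and 3, and the replication list in 51 and 10. A small shift caused by FOXA1 stays open as the biological explanation.

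Hypoxia and glycolysis genes varied together within both groups. The normalization is argued against: with median centring in place of quantile normalization their SD within groups was 1.04 times as large. Array brightness is argued against as the whole reason: GFP 3 and FOXA1 3, the highest for the list, had the lowest and the highest median intensity (7.31 and 7.63), GFP 2 with 7.32 had a list mean of -0.34, and Spearman's rho of list mean and median intensity was 0.147 (permutation p = 0.650, 95% interval from -0.466 to 0.665), with Pearson's r at 0.157 (permutation p = 0.621) and 0.0761 without the 2 farthest arrays, adjusted p = 0.650 for both over 2 coefficients. FOXA1 overexpression is argued against as the reason for this variation by the GFP arrays, which were given no FOXA1 plasmid. Their list means ran from -0.34 on GFP 2 to 0.78 on GFP 3. A difference between the groups is a separate question. It was 0.0108, with a 95% interval from -0.523 to 0.545 that left a difference open, against an SD within groups of 0.415. Compared by number, the interval ran from -0.0563 to 0.0780, but it rests on numbers that are not taken as a pairing. A step shared by arrays of one replicate number may be the reason, since the list means of same-numbered arrays followed each other with r = 0.990 over 6 numbers.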

How the results depend on the processing

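Normexp, the upper quartile filter, the covariate and the fit without 3 arrays were chosen after the data were seen. In limma 0 genes passed in every setting, with 77 to 526 genes or probes at an unadjusted p under 0.05, and the FOXA1 difference stayed between 0.04 and 0.17 without passing. The count of lists past camera was 5 with the authors' table, a variance trend, normexp or the covariate, and 6 with the upper quartile filter. It was 2 with median centring (ribosomal and mitochondrial genes, both lower, in place of the 5), 3 with no filter, 1 with a mean over probes, 3 with array weights, 0 with an estimated correlation, 0 with fry, and 1 without GFP 3, FOXA1 4 and FOXA1 3 (androgen-induced genes); the cause was not tested. Leaving out 1 array gave 0 genes each time, 1 to 5 lists and a FOXA1 difference of 0.07 to 0.17. The list count was 2 without FOXA1 2, 3 without FOXA1 3, 2 without FOXA1 4, 1 without FOXA1 6, 1 without GFP 3 and 2 without GFP 5. Each of the 5 main calls was lost without GFP 3, and the 1 list that passed there was hypoxia and glycolysis genes. GFP 3 had the lowest array weight (0.383) and the lowest mean Pearson's r with the other arrays (0.974).

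Without the 3 arrays TMPRSS2 turned to -0.00766, KLF6 to 0.00684, CHGA to 0.0143, POSTN to 0.0174, and the medians of replication and mitosis genes to -0.00478 and -0.0439. Over single arrays left out, KLK3 ran from -0.0735 to 0.179 (below 0 without FOXA1 3, GFP 2 or GFP 6), SPARC from -0.0999 to 0.000609 (FOXA1 4), P4HA2 from -0.240 to 0.0283 and ADM from -0.209 to 0.0556 (GFP 3). Median centring turned the sign of 5 list medians, none over 0.0409 in size: interferon, mesenchymal, neuroendocrine, luminal secretory and leukocyte lists. It moved the median of all genes to 0.04. With 1 array left out, 41 of 72 gene differences named here moved by over 1.5 times, 4 of them turning sign, as did all 24 list medians, 12 of them turning sign, none of the 5 past camera among these 12.

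With the replicate number as a block, 0 genes passed, 342 had an unadjusted p under 0.05, the FOXA1 difference was 0.13 and 6 lists passed, the 5 and the androgen-repressed list (adjusted p = 0.0222); with an estimated correlation under the block the lowest adjusted p was 0.523. Residual correlations of same-numbered arrays were 0.203, 0.269, 0.530, -0.266, 0.637 and 0.244. Of these, 5 of 6 lay above 0.1, against a median of -0.0674 for other pairs, while 2 of 6 FOXA1 arrays matched their own number best. This evidence is mixed and the labels state no pairing, so the numbers are not taken as a pairing of the design. Results by number stand beside the main fit.

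A filter on detection p and a chip block were not run, since the tables used name neither. Quantile normalization without background correction is the main setting. Signal over background limits dim genes: 32.8% to 36.4% of an array's probes stood above the 95th percentile of its background probes before normalization.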

Other observations

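The tests of same-numbered arrays below were chosen after the results were seen.

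Interferon-stimulated genes were 0.41 above the mean of all arrays on GFP 5 and 0.39 on FOXA1 5, against -0.18 on GFP 4 and -0.16 on FOXA1 4. Polyadenylated histone genes were at 0.53 and 0.45 on the arrays of number 5 and at 0.28 and 0.30 on those of number 6. Unfolded protein response and ATF4 genes were at 0.40 on GFP 3 and 0.33 on FOXA1 3, the arrays with the highest hypoxia and glycolysis genes, and at -0.27 and -0.25 on the arrays of number 2.

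The hypothesis that arrays of one replicate number shared a culture, a day or a handling step was tested on the means of all 24 lists, pairing FOXA1 and GFP arrays by number against all 720 pairings, two-sided. For hypoxia and glycolysis genes r was 0.990 (exact p = 0.00278, adjusted p = 0.0333 by Benjamini-Hochberg over the 24 exact tests) and Spearman's rho was 0.943 (exact p = 0.0167), with r = 0.915 without numbers 3 and 4. For interferon-stimulated genes r was 0.993 (exact p = 0.00139, the smallest that 720 pairings give, adjusted p = 0.0333) and rho was 1 (exact p = 0.00278), with r = 0.998 without numbers 5 and 6. For these 2 lists the values fit the hypothesis, and 2 of 24 lists passed. Over the 24 lists r was positive throughout, from 0.0913 (ribosomal protein genes) to 0.993. Over all genes, the mean residual correlation of same-numbered arrays was 0.270, and 28 of 720 pairings gave as high a mean (exact one-sided p = 0.0389), while number 4 had -0.266. The labels do not say what a number stands for, and no biological explanation was tested.

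Taken by number, the mean of androgen-induced genes was higher in the FOXA1 array for 5 of 6 numbers, by 0.08 ± 0.08 (SD of the 6 differences), with an exact sign-flip p of 0.0625, two-sided (adjusted over 24 lists 0.482). The smallest p that 6 numbers can give is 0.0312, which adjustment over 24 lists all but bars from passing, so this test says nothing for or against a list.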
